A study of Ovis aries with 12 samples.

How the data were processed

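Peripheral blood was sampled from adult rams of the Rasa Aragonesa sheep breed (Ovis aries) that the labels class as sexually active (6 rams) or not active (6 rams). Each ram gave 1 library, so the 12 libraries are 12 different animals, and no label gives a batch, a day or a pairing between groups. Per the labels' protocols, blood was drawn into tubes that stabilise RNA, total RNA was extracted, and stranded mRNA libraries with molecular identifiers were sequenced as 151 bp paired-end reads on a NovaSeq 6000.

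The authors deposited 1 table of raw read counts, whole numbers per Ensembl sheep gene identifier and per library. Per the submitters' processing notes, FastQC, STAR 2.7.8a, HTSeq and edgeR were used. The series design text compares active with not active rams using edgeR. The roles of the other tools, the genome build and the annotation release are not given in the sources used here. Neither are the strand setting of the counting and any use of the molecular identifiers. If molecular identifiers were not used to remove duplicate reads, the counts would include PCR copies, and if strand was not used, reads of overlapping genes would be shared between them. Each column was matched to its library by the code in the sample title, and 0 columns were left unmatched. The table held no rows other than gene identifiers.

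The table gives 26478 identifiers and does not pair them with gene symbols. The reference gene table used here (RefSeq, assembly ARS-UI_Ramb_v3.0) holds no Ensembl identifiers, so 0 of them could be matched to it. Genes are therefore reported by identifier, without position or function. For the same reason the values of CRYL1 and SORCS2, which the series title names, and the planned tests of cell type and pathway gene lists, cell type marker scores and globin share were not analysed here.

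The comparison, active minus not active rams, was fitted to the deposited counts with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (minimum count of 10, minimum total count of 15), libraries were scaled by TMM, and the quasi-likelihood test with robust estimation was applied with the group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and the threshold was an adjusted p of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Levels are TMM-normalised counts per M (CPM), given as mean ± SD over rams. Single values per library (totals, shares, component scores) were compared by exact two-sided permutation tests over all assignments of 12 rams to 2 groups of 6, for which the smallest possible p is 0.0022. Principal components and distances used log2 CPM with a prior count of 2.

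The rule for named genes, fixed before the data were examined, named every gene past the threshold, then genes with a symbol and the smallest unadjusted p, CRYL1, SORCS2 and members of the gene lists, and let a few genes without a symbol be named by identifier in each direction. Since no gene passed and no symbol was matched, the 2 identifiers with the smallest p in each direction are named.

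Library totals ran from 13698096 to 72826372 counts. On simulated counts for the 14374 tested genes (5 simulations with 200 changed genes each, at the observed depths and dispersions), the test called 26.0% of genes changed 1.5-fold, 59.1% of those changed 2-fold and 87.9% of those changed 4-fold, and 3.36% of its calls were false. The simulated genes were drawn independently of each other. All 66 pairs of libraries differed by more than counting noise (median chi-square at least 14.5 times that of counting noise), so none was treated as a duplicate. Alternatives fixed before the data were examined were other scalings (RLE, upper quartile, library totals only), no filter or a stricter one (1 CPM in at least 6 libraries), DESeq2 1.42.0 with its own size factors and filter, from all genes with a count in any library, the edgeR likelihood ratio and exact tests, limma-voom 3.58.1 with and without sample weights, no robust estimation, a surrogate variable (sva 3.50.0), an adjusted p threshold of 0.10, and leaving out each ram.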

Results

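Blood transcriptomes were measured by RNA-seq in 6 sexually active and 6 not active Rasa Aragonesa rams, with 1 library per animal. The comparison asked which genes of circulating blood differ in expression between rams of the 2 behavioural classes. Totals ranged from 42692497 to 72826372 counts (42.7 to 72.8 M) in 11 libraries, and the library of active ram 1 held 13698096 counts (13.7 M). Of 26478 gene identifiers, 5843 had no count in any library and 14374 passed the filter on low counts.

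The clearest difference between the groups was in ENSOARG00020004947, which was measured at 5.80 ± 0.919 CPM (SD, n = 6) in active rams and 32.6 ± 13.1 CPM (SD, n = 6) in not active rams. All 6 active rams lay between 4.92 and 7.36 CPM. In the not active group, 5 rams lay between 33.9 and 44.0 CPM, and ram 7 was at 6.91 CPM, within the range of the active rams. The fitted log2 fold change was -2.48 (SE 0.34), a 5.59-fold lower level in active rams, with an adjusted p of 0.111 by edgeR's quasi-likelihood test. This gene therefore did not pass the threshold of 0.05. Without ram 7 its log2 fold change was -2.69 with an adjusted p of 1.39e-06 by the same test, while leaving out any 1 of the other 11 rams gave an adjusted p from 0.322 to 0.555. The gene was picked by its small p, and ram 7 is its only ram at the level of the other group. Leaving that ram out removes all overlap, so the lower adjusted p without it adds no support. Over 27 alternative settings the log2 fold change ran from -2.69 to -2.29 and the adjusted p from 3.14e-10 with DESeq2's Wald test on the same 14374 genes to 0.958 with limma-voom.

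The other gene of smallest p at lower level in active rams was ENSOARG00020025518, at 19.4 ± 7.76 CPM against 48.1 ± 19.8 CPM (SD, n = 6 each). Its log2 fold change was -1.31 (SE 0.30), and its values overlapped between groups, with a highest active ram of 32.5 CPM and a lowest not active ram of 28.4 CPM. ENSOARG00020010444 was at 9.51 ± 3.29 CPM in active and 3.48 ± 1.49 CPM in not active rams (SD, n = 6 each), a log2 fold change of 1.45 (SE 0.32). ENSOARG00020001266 differed by less, at 27.6 ± 2.69 against 20.9 ± 2.19 CPM (SD, n = 6 each) and a log2 fold change of 0.40 (SE 0.09). The groups also overlapped in ENSOARG00020010444 (lowest active ram 5.16 CPM, highest not active ram 5.80 CPM) and in ENSOARG00020001266 (24.1 and 24.6 CPM). In each of these 3 genes, all 6 active rams were on the same side of the mean of the not active rams. Since the genes were picked by their small p, this adds no support. The adjusted p of each was 0.845 by edgeR's quasi-likelihood test. With DESeq2's Wald test and its own filter, ENSOARG00020010444 (adjusted p = 0.0163) and ENSOARG00020025518 (adjusted p = 0.0256) passed the threshold, although over 27 alternatives the highest adjusted p of both was 0.997. That test also called at least 1 gene in 36 of 40 divisions of the rams into 2 groups of 6, the real one included. ENSOARG00020001266 did not pass it under any of these alternatives (adjusted p from 0.0627 to 0.997).

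**Figure D1:**
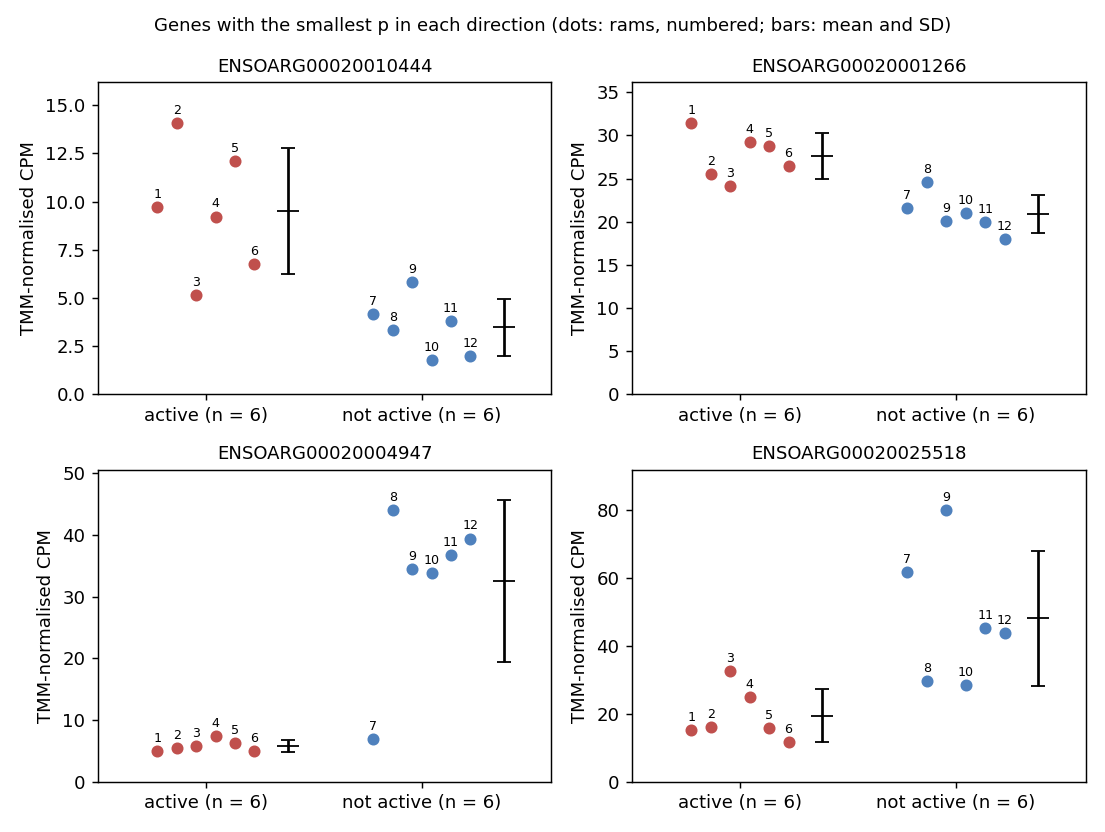
TMM-normalised CPM (vertical axes, from 0) of the 2 genes with the smallest p in each direction, in 6 active and 6 not active rams; each dot is 1 ram with its number, and bars give the mean and SD. For ENSOARG00020004947, not active ram 7 sits at 6.91 CPM among the active rams, below the 33.9 to 44.0 CPM of the other not active rams.

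Across all 14374 genes, edgeR's quasi-likelihood test called 0 genes at an adjusted p of 0.05 and 0 at 0.10. At an unadjusted p under 0.05 there were 805 genes by the same test, where 719 is 5% of the tested genes. Other divisions of the rams into 2 groups of 6 gave a median of 742 genes. With 1 ram left out, the number ran from 559 (without not active ram 7) to 1499 (without active ram 3), so it lay on either side of both values. The likelihood ratio and exact tests of edgeR each called 1 gene, ENSOARG00020004947, and limma-voom called 0 with or without sample weights, all on the same 14374 genes. DESeq2's Wald test, fitted to these genes, gave 14147 of them an adjusted p and called 6, 2 at a higher and 4 at a lower level in active rams. With its own filter in place of that of edgeR, starting from 20635 genes, it gave 15522 an adjusted p. It then called 13 genes (8 higher, 5 lower), which include the 6. Without active ram 1 it called 20 genes with its own filter, of which 10 were among the 13. In 20 genes the 2 groups did not overlap in CPM, which is 0.139% of tested genes, against 0.216% given by chance. No gene was at 1 CPM or more in all rams of one group and under 0.1 CPM in all rams of the other.

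Of the 805 genes, 586 were at a higher and 219 at a lower level in active rams. Without active ram 1, 457 of 814 genes (56.1%) were at a higher level in active rams, against 72.8% with all rams. The share was 73.03% with RLE and 67.6% with upper-quartile scaling, but 48.1% (275 of 572 genes) with library totals alone, which do not correct for composition. Scaling by totals moved the median log2 fold change of all genes from 0.0093 to -0.103. Fitted differences over 2-fold were found in 594 genes at a higher and 51 at a lower level in active rams with all 12 rams, and in 386 and 78 genes without active ram 1.

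The median standard error of a log2 fold change was 0.15. For 11391 genes (79.2%), an approximate 95% interval of the fold change lay within a 2-fold difference in either direction. In counts simulated at the observed depths and dispersions, the same test called 59.1% of genes changed 2-fold and 26.0% of genes changed 1.5-fold. These simulations held 200 changed genes each and drew every gene independently, so the differences that many genes share between rams were absent. The adjusted p also depends on how many genes change, so these rates need not hold for the real comparison.

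No separation of the libraries by group as a whole was detected. The group accounted for 11.9% of the variance of log2 CPM between libraries (exact permutation p = 0.102). With 1 ram left out, the share ran from 10.9% (without not active ram 11, exact permutation p = 0.262) to 15.9% (without active ram 1, exact permutation p = 0.0693). The first principal component (29.8% of variance) set active ram 1 apart, at a score of 108 against -38.8 to 12.5 in the other 11 rams. On the second component (21.04% of variance), active rams averaged 20.3 ± 25.9 and not active rams -20.3 ± 25.2 (SD, n = 6 each; exact permutation p = 0.0281, adjusted p = 0.169 over 6 components). The 4 lowest scores on this component were those of not active rams 7, 8, 10 and 11, while not active rams 9 and 12 lay among the active rams.

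Active ram 1 differed from every other library in makeup. Its largest gene, ENSOARG00020023746, named after its values were seen, held 6.13% of its counts (95% Wilson interval 6.12% to 6.15%, counting error only), while the largest gene of any other library held at most 0.952%. The 10 largest genes held 19.8% of the counts of active ram 1 (95% Wilson interval 19.76% to 19.81%) and 3.93% to 4.80% in the other 11 libraries. In active ram 1, 307 genes were more than 4-fold above every other library and 94 more than 4-fold below, against at most 12 and 10 genes in any other library. Those 307 genes held 32.7% of its counts (95% Wilson interval 32.64% to 32.69%) and 2.52% to 2.93% of the counts of the other libraries. No group difference was detected in library totals (45.2 ± 16.4 M in active and 52.9 ± 10.2 M in not active rams, SD, n = 6 each, exact permutation p = 0.431, adjusted p = 0.538). None was detected in the share of the largest gene either (1.71% ± 2.17 against 0.778% ± 0.0788, SD, n = 6 each, exact permutation p = 0.190, adjusted p = 0.317), with 5 library measures tested. Without active ram 1, the share of the largest gene differed by 0.0501 percentage points (exact permutation p = 0.366). The difference in mean library total, active minus not active, was -7.71 M with all rams. It was -1.41 M without active ram 1 (exact permutation p = 0.838).

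**Figure D2:**
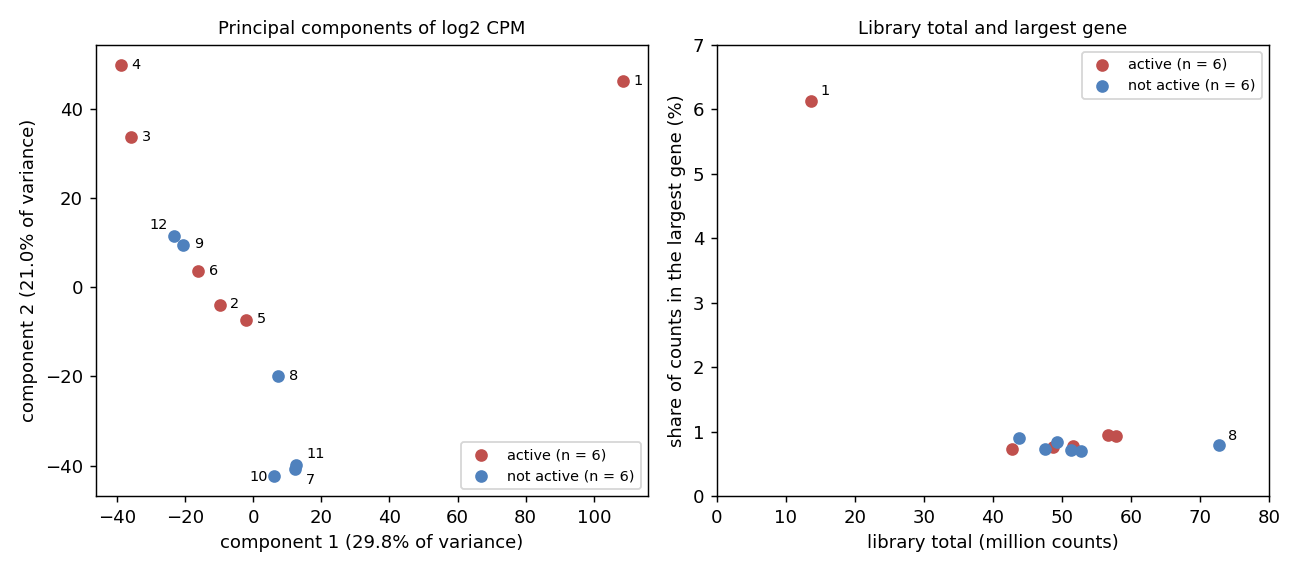
Left, scores of the 12 libraries on the first and second principal components of log2 CPM (29.8% and 21.04% of variance), numbered by ram; right, the library total in M counts against the share of counts in the largest gene in percent. Active ram 1 sits alone in both plots, at 13.7 M counts and 6.13%, and not active ram 8 has the highest total, at 72.8 M.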

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

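Of the tests in this part, the lowest count of and the chance alignment for ENSOARG00020004947, the comparison of active ram 1 with the other active rams and the bound from its 10 largest genes were chosen after the results were seen. Single rams far from the rest of their group were looked for in 18 sets of 6 values, and 7 were found, where chance would give about 1 set in 20. The sets were not independent. Most of the 7 were linked measures of the library of active ram 1, and some sets were genes picked by small p. The 7 therefore cannot be weighed against chance as separate events. Not active ram 8 had 72.8 M counts, against 43.8 to 52.8 M in the other not active rams.

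Active ram 1 was apart from the other active rams in its library total (13.7 M against 42.7 to 57.8 M), its number of genes detected (15638 against 17489 to 17905), its TMM factor (0.640 against 1.00 to 1.07), its largest gene (6.13% of counts against 0.728% to 0.952%) and its 10 largest genes (19.8% against 4.18% to 4.80%). Low depth is argued against as the source of the 307 genes more than 4-fold above all other libraries, since any other library thinned to the same total had at most 11 such genes. A few abundant genes taking the counts do not account for the 94 genes more than 4-fold below all other libraries, since the share of its 10 largest genes could lower the other genes by at most 1.25-fold. Low depth was not tested for these 94 genes and stays open for them, since the thinned libraries were searched for higher genes only. Membership of the active group was examined in the 338 genes more than 4-fold higher in active ram 1 than in every not active ram. The choice did not use the other 5 active rams, but 307 of the 338 are the genes above all other libraries. That those 5 rams lay below active ram 1 was therefore largely given in advance. How far they lay from the not active mean was not. Their medians lay from -0.038 to 0.15 log2 units from it (median ram 0.055), against 3.68 for active ram 1. This argues against group membership as the whole source. A different mix of blood cells, a condition of that animal or the handling of that sample stay open, and without gene names they could not be tested.

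ENSOARG00020004947 was at 6.91 CPM in not active ram 7, against 33.9 to 44.0 CPM in the other not active rams and 4.92 to 7.36 CPM in the active rams. Low counts are argued against, since every ram had at least 43 counts. A wrong label of ram 7 stays open: it lay nearer the active mean in 27 of the 100 genes of smallest p in a fit without it, the lowest number of the 12 rams, and its component 2 score (-40.8) lay with those of not active rams 10 and 11 (-42.2 and -39.9), both on the side of its label. This does not exclude a wrong label, since 10 of the 11 other rams lay nearer the opposite group in more than 50 genes and the groups overlap on component 2. Chance alignment remains open too: 41 genes had such separated levels, of which 1, this gene, aligned this well with the groups, and in a share of 0.139 of all possible group assignments at least 1 of them would align as well (Fisher's exact p = 0.0152 for this gene alone, two-sided). An inherited difference between rams, a relation to sexual activity and reads shared with a similar gene also stay open, as untested hypotheses.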

How the results depend on the processing

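The alternatives for component 2, the share of variance between groups and the library measures, the fit without both active ram 1 and not active ram 7, DESeq2 without active ram 1 and DESeq2 on the genes of the main filter were chosen after the data were seen. The count of changed genes, 0 with the main settings, stayed 0 under RLE, upper-quartile or total scaling, no filter, the stricter filter, both limma-voom fits, no robust estimation, the surrogate variable and an adjusted p of 0.10. It was 13 with DESeq2 and its own filter, from 20635 genes (8 higher, 5 lower), 6 with DESeq2 on the 14374 genes of the main filter (2 higher, 4 lower), 20 with DESeq2 and its own filter without active ram 1, from 20611 genes (12 higher, 8 lower), 1 with the likelihood ratio test (lower), 1 with the exact test (lower) and 1 without both active ram 1 and not active ram 7 (lower); the cause was not tested. Leaving out single rams gave 0 to 1 changed genes and 0 to 1 lower genes, the 1 being ENSOARG00020004947 without not active ram 7. Its log2 fold change ran from -2.69 to -2.29 over 27 alternatives, with adjusted p from 3.14e-10 (DESeq2 on the genes of the main filter) to 0.958 (limma-voom), past the threshold in 7 of them. The log2 fold changes of the other 3 named genes kept their sign in all 27 alternatives. Genes at an unadjusted p under 0.05 numbered 559 to 1499 with 1 ram left out, the highest without active ram 3 (805 with all rams). The group difference on component 2 had exact permutation p from 0.0195 to 0.0887 with 1 ram left out and lay above 0.05 without active ram 1 (p = 0.0563, where the matching component ranked as component 1) or 4 or not active ram 7, 10 or 11. Alternatives that need gene names (gene lists, marker scores, the leukocyte covariate, removal of globin, immunoglobulin and mitochondrial genes, CRYL1 and SORCS2) were not run. With 13.7 M counts, active ram 1 measures low genes less precisely than the other libraries.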

Other observations

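The search for genes with separated levels and the carry-over test were chosen after the result was seen. Counting ENSOARG00020004947, 41 genes had expression in 2 separated levels across the 12 rams, defined as a gap of more than 1 log2 unit that exceeds the range within either level, with at least 3 rams in each and a mean log2 CPM above 0. The median gap over the 41 genes was 1.89 log2 units. Apart from ENSOARG00020004947 (Fisher's exact p = 0.0152, two-sided), the lowest p for alignment with the groups was 0.0801 by the same test, none of them adjusted for the 41 genes.

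The largest gene of active ram 1, ENSOARG00020023746, had 840202 counts there, 14118 in not active ram 8 and 72 to 635 in the other 10 libraries. Over all 307 genes of active ram 1, not active ram 8 was the highest of the other 11 libraries in 42 genes (13.7%, against 9.09% by chance). This was fewer than in not active ram 7 (48 genes) or active ram 4 (47 genes). In genes that the other libraries also express, a rise of under 1% of the level in active ram 1 could be hidden by differences between rams. The count therefore cannot show how much of the set rose in not active ram 8. Carry-over of 1 library into the other would give every abundant gene the same share of its level in active ram 1. Of 58 genes of the set above 1000 CPM in active ram 1, 5 had a median under 0.25% of that level in the other 10 libraries, a limit set after all 58 had been looked at. Among these 5, the excess in not active ram 8 ran from 0.0966% (0.0510% to 0.109%) to 0.801% (0.420% to 0.953%), with bounds from the 95% counting interval and the lowest and highest of the other 10 libraries as background, which argues against carry-over as the whole source. What raised these 5 genes in not active ram 8 stays open, and no biological explanation was tested.

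The number of genes was also counted for 100 splits of the 12 rams into 2 groups of 6, the real split included, drawn from the 462 that exist. With edgeR's quasi-likelihood test at an adjusted p of 0.05, the real split gave 0 genes, which all 100 splits reach by construction, so this count says nothing about chance (highest other split, 2 genes). Chance cannot be excluded for the other results. At an unadjusted p under 0.05, 37 of the 100 splits, counting the real one, gave at least its 805 genes, and 8, counting the real one, gave a smallest p as low as its 7.75e-06 (lowest other, 6.58e-08). With DESeq2's Wald test and its own filter, 18 of 40 splits, counting the real one, gave at least its 13 genes, with a highest other count of 119. At least 1 gene was called in 36 of these 40 splits, and the median of the other splits was 8 genes. The highest other count at an unadjusted p under 0.05 was 3016, for rams 1, 2, 4, 5, 7 and 10 against the rest, which passed no gene at an adjusted p of 0.05. It may point to a structure among the rams apart from the behavioural labels, but this split was picked as the highest of those drawn and the structure was not tested.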
